A study of Mus musculus with 4 samples.

How the data were processed

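The samples were 2 CTCF immunoprecipitations and 2 inputs from primary mouse cortical neurons, grown from embryonic day 16 cortex for 13 days. Per the labels' protocols, each replicate held about 15M cells, fixed for 10 minutes in formaldehyde at 1%, and DNA fragments after sonication measured 200 to 500 bp. The labels' culture text mentions a drug, but these samples carry no treatment. Per the submitters' processing notes, the tools were FastQC, Trimmomatic, BWA, SAMtools and MACS2, and the builds mm10 and GRCm38.p6, without versions or roles. The MACS2 threshold and how inputs were used are not given in the sources used here.

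The deposited file is a table of 20 columns in the layout that the IDR program writes for a pair of replicates. The −log10 p of each replicate's matched peak and their sum, the joint strength, are deposited values made by the authors, and they depend on each library's depth. The sum was checked in all 33820 rows. The deposited score is a rescaled IDR. The lowest −log10 of the global IDR was 1.30, the threshold of 0.05, and 24.8% of peaks stood at the cap of 5. By this layout, peaks were called per replicate and then joined. The file does not tie its replicate columns to a labelled replicate, so they are called the first and second replicate column. The list holds no input values, so inputs could enter only through the authors' peak calling. Depth per library is unknown, so a higher value in one column can come from depth alone. Strengths are compared only within this list, between classes of peaks and chromosomes, and used to rank and filter peaks.

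Genes came from a RefSeq gene table of GRCm38.p6, the build of the peaks, with the start and end of each gene but no strand, transcripts or exons. The 348 genes whose coordinates run on scaffolds were left out, 113 of them protein-coding, which left 49595 genes, 21774 protein-coding. No genome sequence was used here. The design fixed before the data were examined set promoter windows at transcription start sites, exon and UTR classes, and motif tests, and said that annotation would not be done without a genome. With the gene table supplied, a reduced annotation was made. The promoter became the 1 kb on either side of each end of a protein-coding gene, so an end can be a start or a finish. Summits were classed in this order: gene end, elsewhere inside a protein-coding gene, within 1 kb of another gene or inside it, intergenic. Motifs, motif orientation, exons and UTRs were not analysed here. Chromosome spans ran from the first to the last base of a gene or peak, gaps included.

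Class shares were tested by 1000 circular shifts of the peaks within each chromosome (two-sided permutation). Gene lists, fixed before the data were examined, were tested with two-sided Fisher exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 16 lists; all listed symbols were found. Genes of a cluster can share peaks, so those p-values treat as independent what is not. Length trends used Spearman's rho across genes and strength differences of medians, each with 100000 permutations, and intervals came from 1000 bootstrap draws; the 9 strength tests were adjusted together. Genes and peaks are not replicates, and p-values describe this list, not the spread between cultures. Binomial and Poisson intervals are exact, at 95%, and cover counting error only. Counts at the 23 loci against shifts, spacing between neighbours and the relation to gene density were added after the data were seen. Named genes followed a fixed rule: per list the 3 with the strongest end peak, the 10 strongest end peaks of all, the 10 genes with the most peaks inside, the 5 densest of 100 kb or more, fixed loci, and the 10 strongest peaks. Fos, the single beta and alpha protocadherins and other members beyond that rule were named to fill counts, after their values were seen. Some genes that the rule names are not reported here.

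Alternatives were peaks above the median strength, an IDR of 0.01, any base of the peak instead of its summit, windows of 500 bp and 5 kb, uniform placement, shifts for the lists, lists matched on gene length, unshared ends and each replicate column alone. Length trends were also run without clustered gene families (olfactory and vomeronasal receptors, Zfp genes and clustered protocadherins). Alternatives used 10000 permutations. The code was tested on simulated data: with no planted excess, gene ends stood at 1.00-fold over shifted positions for 33815 simulated peaks. With 10% planted, the share at ends was 12.9%. Of 40 random gene lists 0 were called, while a planted list of 100 genes was. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.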

Results

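CTCF occupancy was profiled by chromatin immunoprecipitation and sequencing in cultured mouse cortical neurons, as part of a study of the topoisomerase TOP2B in neurons. CTCF is a zinc finger protein that binds DNA and, together with the cohesin complex, shapes chromatin loops. The neurons came from embryonic day 16 Swiss-Webster cortex and were collected after 13 days in culture, without treatment. There were 2 CTCF immunoprecipitations, labelled as biological replicates, and 2 input libraries. The deposited data analysed here are 1 joint list of 33820 peaks, each found in both replicates at an irreproducible discovery rate (IDR) of at most 0.05. Of these, 33815 lay on the assembled chromosomes and 5 on unplaced contigs. With 1 condition there was no comparison between groups of samples, so every comparison below is between classes of peaks or genes within this list. The read depth of each library is unknown from the list, so no interval below covers it.

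Peaks had a median width of 1123 bp, from 348 to 6943 bp, and covered 41.6 Mb in all. The strength of a joint peak is the authors' value, the sum of the −log10 p of both replicates. The strongest peak on a chromosome, at chromosome 6 from 47650529 to 47651611 (mm10), had a strength of 6692.5 and lay within the predicted gene Gm40371. The strongest peaks at ends of protein-coding genes were those at Nipsnap2 (chromosome 5, 129723874 to 129725901, strength 3601), Sh3glb1 (chromosome 3, 144719280 to 144721169, strength 3382) and Vps36 (chromosome 8, 22191951 to 22193661, strength 2870). Sh3glb1 encodes a membrane-curving endophilin and Vps36 a subunit of an endosomal sorting complex. The 10 strongest peaks also included one inside Cilk1 on chromosome 9 (2741), one at Gm40715 on chromosome 10 (2676) and one on Y from 90802807 to 90806503 (3409). At Nipsnap2 the replicate values were 1791 and 1810. Over the whole list the median −log10 p was 30.87 in the first replicate column and 128.88 in the second, and 90.7% of peaks were stronger in the second. Over all peaks the columns correlated with a Spearman rho of 0.648, a description only, since the peaks were selected for agreement and are not independent replicates. Summits of the matched replicate peaks lay a median of 29 bp apart. Neighbouring joint summits were a median of 26.8 kb apart, against 50.1 ± 0.28 kb (SD over 1000 uniform placements; two-sided permutation p = 0.002, the smallest these placements can give).

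The first question was where in the genome of these neurons CTCF sat. Peaks gathered at the ends of protein-coding genes. Within 1 kb of either end lay 6096 summits, 18.03% of the list, against 3.22% ± 0.14 (SD over 1000 circular shifts), a 5.6-fold excess. It was 7.35-fold with windows of 500 bp and 2.86-fold with 5 kb. Among peaks above the median of the first replicate column it was 7.69-fold, and of the second 4.87-fold. The excess was steepest close to the end: 9.75-fold within 100 bp and 3.69-fold between 500 and 1000 bp. The 10 genes with the strongest end peak were Nipsnap2, Sh3glb1, Vps36, Gdf15, Ap5s1, Vps18, Pkn3, Apba1, Erlin2 and Zbtb45, with strengths from 3601 down to 2253. Vps18 and Vps36 act in endosomal sorting, and Gdf15 is a secreted stress-induced cytokine. In all, 6349 of 21774 protein-coding genes (29.2%) had a peak at an end.

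Another 14737 summits (43.6%) lay deeper inside protein-coding genes, 1.11-fold over shifted positions (39.4% ± 0.71). Gse1, a gene of 352883 bp on chromosome 8 (120228501 to 120581383), held the most, 28 peaks, followed by the transcription factor gene Camta1 with 26. Nav2 held 19, Agap1 18, and Asic2, Pde4d and the synaptic scaffold gene Shank2 17 each. The other genes among the 10 with the most were Gm37013, Gm38666 and Gm38667, predicted genes that span the protocadherin cluster. Among genes of 100 kb or more the densest were 2900026A02Rik (8.27 per 100 kb), Tacc1 (8.01), Gse1 (7.98), Myo18a (7.94) and Wnt5b (7.25). Other genes, mostly non-coding, held 8.51% of summits, 0.91-fold of shifted positions. Intergenic sequence held 29.9% against 48.0% ± 0.75, which is 0.62-fold. All 4 shares differed from the shifts (two-sided permutation, Benjamini-Hochberg adjusted p = 0.002, the smallest 1000 shifts can give). The share at other genes did not pass among peaks above the median strength (0.96-fold, permutation adjusted p = 0.23) or of the second column (0.99-fold, permutation adjusted p = 0.737). The excess inside genes did not pass the test among peaks above the median strength (1.04-fold, permutation adjusted p = 0.080; up to 0.691 over its alternatives). It turned to 0.94-fold when gene ends were drawn at 5 kb, a setting that moves the surroundings of the ends out of this class.

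**Figure D1:**
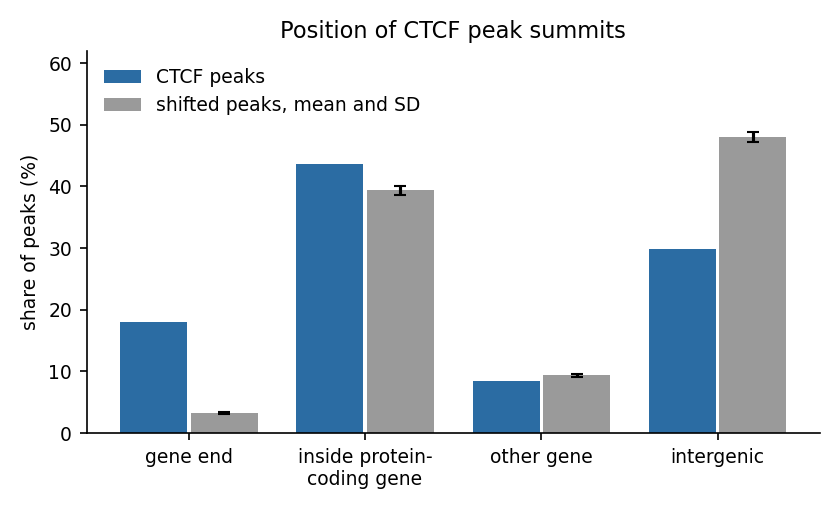
Share of CTCF peak summits (%, vertical axis) in 4 classes of position, for the observed peaks (blue bars) and for the mean of 1000 circular shifts (grey bars, error bars ± SD). Gene ends held 18.03% of summits against 3.22% after shifting, and intergenic sequence 29.9% against 48.0%.

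Next, 16 lists of genes were compared with the other protein-coding genes for the share with a peak at either end. Clustered protocadherins, cell-surface proteins that give neurons their identity, had the highest share, 38 of 57 genes (66.7%, exact Clopper-Pearson 95% interval 52.9 to 78.6) against 29.1% of others (Fisher exact test, adjusted p = 4.2e-08). This count takes 21 gamma genes through 1 shared peak. Counting only ends that no other gene shares, 20 of 55 clustered protocadherins had a peak (36.4% against 24.0% of others), which did not pass the test (Fisher adjusted p = 0.104). By this count long neuronal genes had the highest share, 62.5%. It also leaves out the peaks at Pcdha4, Pcdha6 and Pcdha7, whose lower ends lie beside those of the predicted genes Gm37013, Gm38666 and Gm38667. Among peaks above the median of the second replicate column the list lay below other genes (−11.4 points, Fisher adjusted p = 0.021), so its direction cannot be given for both columns. The shared gamma peak lay above the median of the first column and below that of the second, so the difference between columns rests largely on 1 peak. Long neuronal genes had 26 of 40 (65.0%, interval 48.3 to 79.4, Fisher adjusted p = 1.5e-05). Random lists matched on the decile of gene length had a mean of 43.1%, 21.9 points lower (permutation over random lists, adjusted p = 0.025). The top decile also holds genes under 300 kb, and the 557 genes over 300 kb stood at 47.8%. Length is therefore not fully matched for the longest genes, and the excess beyond length may be smaller. The strongest end peaks of long neuronal genes were at Wwox (strength 1301), the adhesion molecule gene Lsamp (907) and the potassium channel partner gene Kcnip4 (721). Among peaks above the median strength this list had 27.5% and did not pass (Fisher exact test, adjusted p = 0.132; 1.3e-06 to 0.438 over its alternatives). Above the median of the second column alone the difference was 6.89 points and did not pass (Fisher exact test, adjusted p = 0.438), while by the first it was 34.0 points (Fisher exact test, adjusted p = 1.4e-05). Ribosomal protein genes, found by symbol, came next with 47 of 98 (48.0%, interval 37.8 to 58.3, Fisher adjusted p = 0.00026), with strong peaks at Rps3a1 (1630) and Rplp0 (1537). Among peaks above the median of the first column their excess was 10.6 points (Fisher adjusted p = 0.042), and of the second 17.6 points (Fisher adjusted p = 3.1e-05), against 18.9 points in the whole list. Without kinases and retrogene-like symbols that the same pattern caught, the share was 39 of 77 (50.6%). The chemoreceptor families lay at the other extreme. Only 7 of 1109 olfactory receptor genes (0.63%, interval 0.25 to 1.3) and 1 of 350 vomeronasal receptor genes (0.29%), Vmn2r29, had an end peak (Fisher exact test, adjusted p = 2.3e-155 and 2.2e-50). Random lists matched on the decile of gene length had means of 12.9% and 16.6%. This leaves differences of −12.3 and −16.3 points (permutation over random lists, adjusted p = 0.0008 for both). These random lists could hold genes of the other receptor family, which lowers their means. How much of the deficit goes with short genes therefore cannot be told. The strongest olfactory receptor end peaks were at Olfr1373 (strength 176), Olfr90 (161) and Olfr94 (137).

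The remaining 11 lists did not pass the test after adjustment. With windows of 5 kb Hox genes turned from −6.09 to 20.6 points and passed (Fisher exact test, adjusted p = 0.020). Housekeeping genes (24.4 points) and Zfp genes (−7.59 points) also passed there (Fisher exact test, adjusted p = 0.0065 for both). So did activity-regulated genes (35.4 points, Fisher adjusted p = 0.00022). Neighbouring Hox genes can share 1 peak in such wide windows, so the Fisher test treats linked genes as independent. Activity-regulated genes, which respond to neuronal firing, had end peaks at 14 of 30 members (46.7%, Fisher p = 0.044, adjusted p = 0.116). These included Vgf (strength 997), Dusp1 (620), Junb (551) and Fos (61.1). Counting any base of the peak raised this to 76.7% (Fisher exact test, adjusted p = 3.3e-05; 3.3e-05 to 0.473 over its alternatives), so the call for this list rests on how a peak is assigned to an end. Imprinted protein-coding genes had 14 of 32 (43.8%), with strong peaks at Ascl2 (558) and Peg10 (472), and at the non-coding Peg13 (486), which the share leaves out. Housekeeping genes had 14 of 37 (37.8%), led by Rplp0, Tpi1 (728) and Rpl13a (655). Among 21 genes of cohesin, CTCF and topoisomerases 7 had one, among them the cohesin acetyltransferase gene Esco1 (1254), Pds5b (956) and Stag2 (862). Markers of excitatory neurons had 9 of 30, with Cux2 (1691), Nrgn (968) and Cux1 (820) strongest, and markers of inhibitory neurons 5 of 20, with Calb2 (1433), Gad1 (455) and Pvalb (179). Of the cell types a cortical culture can also hold, markers of oligodendrocytes had 7 of 15, with peaks at Myrf (1129) and Cnp (181) among them. Astrocyte markers had 5 of 15, led by Slc1a3 (226), Slc1a2 (151) and Aldoc (125), and microglial markers 2 of 15, among them C1qa (53.0). Hox genes had 9 of 39, led by Hoxa5 and Hoxa6 at 1 shared peak (387) and Hoxc5 (368). Genes with a Zfp symbol had 108 of 397 (27.2%), led by Zfp398 and Zfp786 at 1 shared peak (1869) and by Zfp319 (1113).

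**Figure D2:**
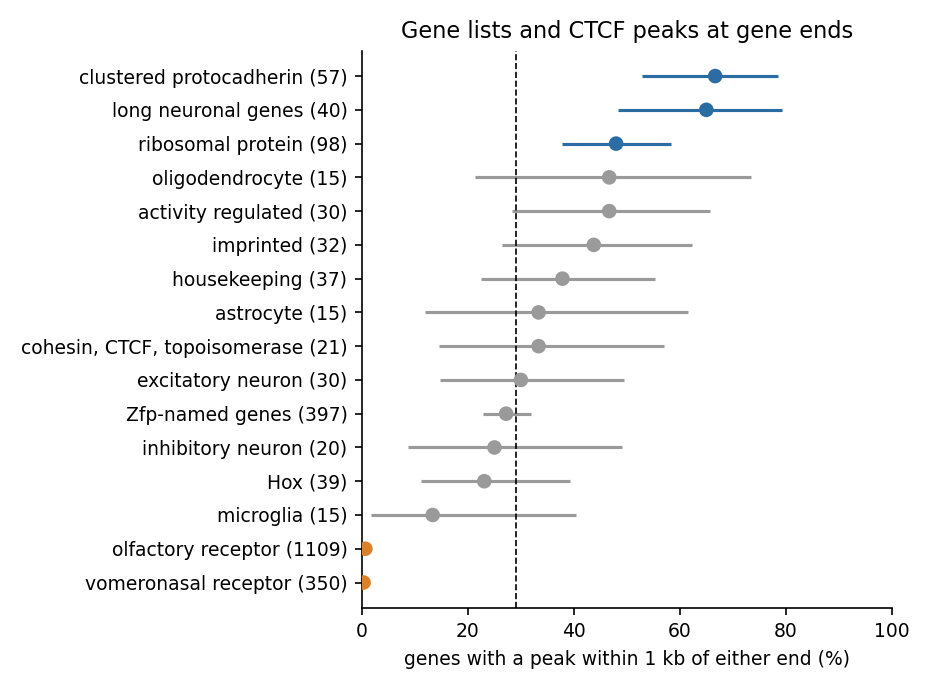
Share of the genes of each list with a CTCF peak within 1 kb of either end (%, horizontal axis; points) with exact 95% binomial intervals (lines), and the number of genes in brackets. Blue and orange lists lay above and below other protein-coding genes after adjustment, grey lists did not pass, and the dashed line marks all protein-coding genes at 29.2%; protocadherins stood at 66.7% and olfactory receptors at 0.63%.

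The protocadherin cluster on chromosome 18, from 36930285 to 37841873, held 28 peaks within 10 kb of its bounds. At the alpha genes, 11 of 14 had a peak at their lower-coordinate end, from Pcdha3 through Pcdha12 and at Pcdhac1, and 3 had none: Pcdha1, Pcdha2 and Pcdhac2. The Pcdhac1 peak (37089434 to 37090980) was the strongest of the cluster at 732, with 372 and 360 in the replicate columns. The other 10 alpha peaks ranged from 40.4 at Pcdha9 to 155 at Pcdha12. Of 22 beta genes, 6 had a peak at their lower-coordinate end: Pcdhb2, Pcdhb3, Pcdhb4, Pcdhb8, Pcdhb10 and Pcdhb16. All 21 gamma genes counted through 1 peak at their shared upper end (37840976 to 37842465, strength 188), and 6 also had one at their own lower end. By the second replicate column alone, among peaks above its median, only 1 of the 57 genes (1.75%) had an end peak, below other genes (−11.4 points, Fisher exact test, adjusted p = 0.021). By the first column 42.1% did, above other genes (21.1 points, Fisher exact test, adjusted p = 0.0018). All 21 gamma genes are in that share through their shared peak, whose value of 79.9 lay above the first column's median of 30.87. Its value of 108.5 in the second column lay below that column's median of 128.88. The excess by the first column therefore rests mainly on 1 peak.

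**Figure D3:**
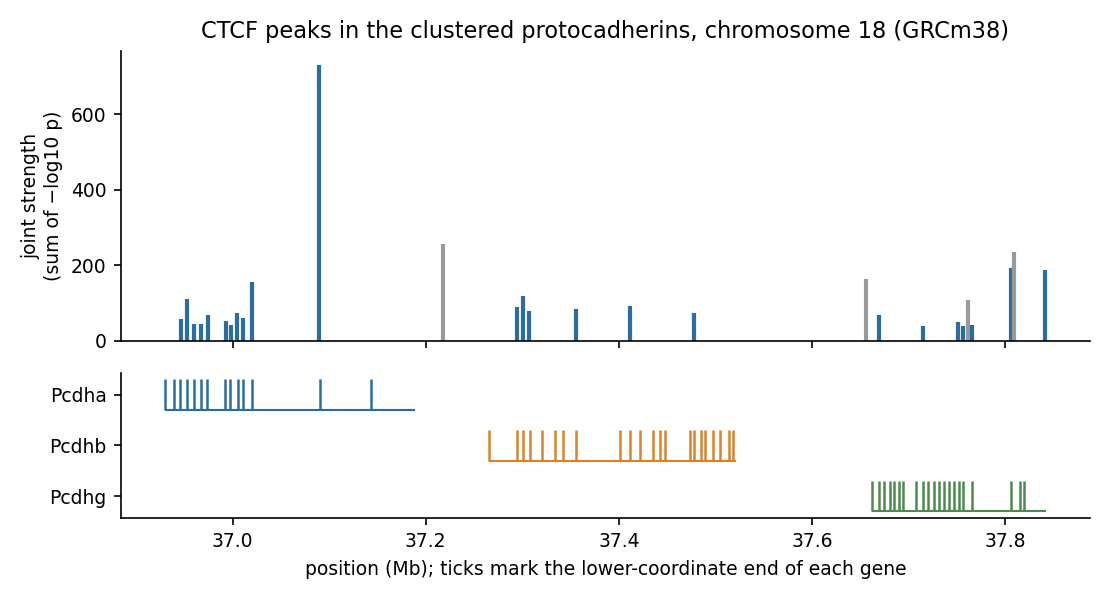
Joint strength of the CTCF peaks (sum of −log10 p of both replicates, vertical axis) along the clustered protocadherins on chromosome 18 (Mb, horizontal axis), with peaks at gene ends in blue and others in grey; ticks in the lower panel mark the lower-coordinate end of each gene. The peak at Pcdhac1 reached 732 and the alpha peaks to its left ranged from 40.4 to 155.

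Fixed loci of neuronal, imprinted and developmental interest were counted with 10 kb on either side. Around the imprinted pair H19 and Igf2 on chromosome 7 there were 7 peaks, of which those at 142580014 to 142582437 (strength 261) and 142670937 to 142673913 (290) were the strongest. The Hoxa, Hoxb, Hoxc and Hoxd clusters held 7, 9, 3 and 8. Hoxa contained the strongest of these, 1340 at 52221189 to 52223071 on chromosome 6. Among activity-regulated loci, Bdnf, a neurotrophin gene, held 4 peaks, Fos and Nr4a1 3 each, Npas4 2 and Egr1 1 (strength 907), while Arc held none. Nrxn3 held 13 peaks and Cntnap2 11. Ctcf itself held 4, the strongest at its end (645), Top2b 3, and Peg3 and Grb10 3 each. Dlx5 and Dlx6 shared 1 (strength 421), and Kcnq1ot1, Meg3 and Rad21 had none. After adjustment over the 23 loci, none of these counts differed from shifted peaks (permutation, smallest adjusted p = 0.444); at an unadjusted p under 0.05 stood Fos (p = 0.026) and Hoxa (p = 0.040). The protocadherin count was 28 against 10.8 ± 8.67 (permutation p = 0.104).

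Long genes are a standing question in work on topoisomerases, so peaks were counted by gene length. Longer genes more often had a peak at an end. The share rose from 21.5% of 7856 genes under 10 kb to 47.8% of 557 genes over 300 kb (exact 95% intervals 20.6 to 22.5 and 43.5 to 52.0), with 29.6%, 33.7% and 41.8% between. Across 21774 genes, which are not independent replicates, Spearman's rho was 0.171 (permutation p = 1e-05, the smallest 100000 permutations can give). It was 0.120 without clustered gene families, 0.089 among peaks above the median strength and 0.064 above the median of the second column (permutation p = 0.0001 for each). Inside genes the density of peaks went the other way. It fell from 3.85 per 100 kb in genes under 10 kb to 0.78 in genes over 300 kb, which is 2.71-fold and 0.59-fold of shifted positions (permutation, adjusted p = 0.0025 for both). All summits stood at 2.27-fold of shifted positions 1000 to 2500 bp from the nearest protein-coding gene end, and at 0.38-fold beyond 50000 bp. Short genes lie near their ends throughout, so the fall cannot be told apart from distance to an end. Lsamp, which spans 2197426 bp, held 15 peaks inside or 0.68 per 100 kb, and Cntnap2 0.45. Single genes could lie far from their class. Bdnf, of 52344 bp, held 7.95 per 100 kb, against 1.93 for genes of 30 to 100 kb together. Gse1, of 352883 bp, held 7.98. The trend per gene had the opposite sign to these totals, rho = 0.142 among 13917 genes of 10 kb or more (permutation p = 1e-05; 0.235 above the median of the second column, permutation p = 0.0001); 91.4% of the longest genes but only 33.1% of genes of 10 to 30 kb had any peak inside.

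Peak strength was then compared between classes. Peaks at gene ends were weaker than intergenic peaks in the joint value, with a median of 160.7 against 181.3, a difference of −20.6 (bootstrap 95% interval −27.5 to −11.7; permutation, adjusted p = 1.5e-05). This direction was that of the second replicate column, with 99.96 against 149.4 (difference −49.4). In the first column gene ends were stronger, 52.9 against 26.7 (difference 26.2, interval 23.9 to 29.01, permutation adjusted p = 1.5e-05). The second column exceeded the first by a median of 0.40 on the log2 scale at gene ends and by 2.26 in intergenic sequence. Peaks inside protein-coding genes had a joint median of 152.2, below intergenic peaks by −29.1 (interval −34.4 to −24.2, permutation adjusted p = 1.5e-05), but stood 1.11 above them in the first column. Peaks at other genes did not differ from intergenic peaks in the joint value (182.0, difference 0.66, interval −9.47 to 10.1), but were stronger in the first column (30.7 against 26.7, difference 3.98, interval 2.04 to 5.53, permutation adjusted p = 1.5e-05). The joint difference at gene ends was 14.5 among peaks with an IDR of 0.01 or below. That cut also selects on strength (gene-end median 239.8 against 160.7), so it cannot decide the direction. The joint difference did not pass when any base of the peak counted (−3.22, permutation adjusted p = 0.351). It did not pass with windows of 5 kb either (−4.79, permutation adjusted p = 0.274). Because the 2 columns disagreed, a direction for gene ends cannot be given for both replicates.

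**Figure D4:**
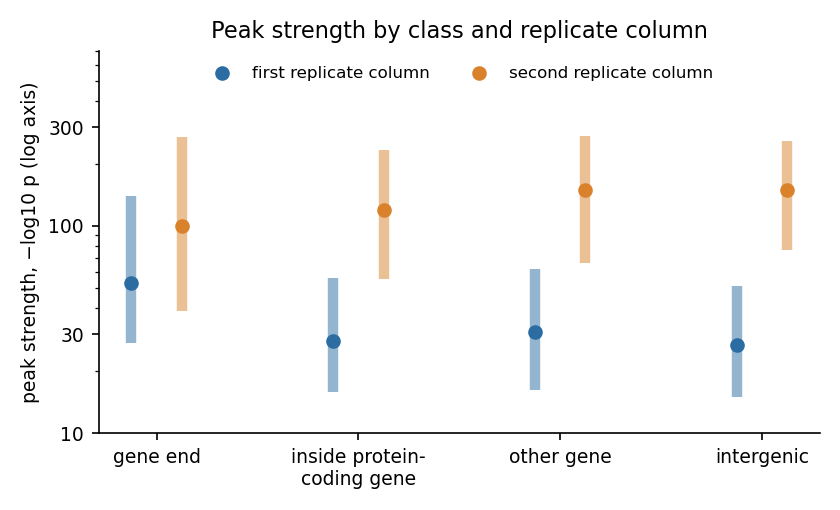
Peak strength in each replicate column (−log10 p, vertical log axis) for 4 classes of position; points are medians and bars span the first to the third quartile. At gene ends the medians were 52.9 and 99.96, against 26.7 and 149.4 in intergenic sequence.

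Chromosomes differed in peak density. The 19 autosomes carried 13.8 peaks per Mb together, from 10.4 on chromosome 3 to 21.3 on chromosome 11. Density rose with that of protein-coding genes (Pearson r = 0.872, Spearman rho = 0.912, permutation p = 1e-05 for each, also adjusted over both). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.893. The X chromosome carried 729 peaks, 4.35 per Mb (exact Poisson 95% interval 4.04 to 4.68), which is 0.316 of the autosomal density (0.293 to 0.340). At X genes, 114 of 963 (11.8%) had an end peak, against 25.1% to 36.2% on single autosomes. X peaks were also weaker, with a median strength of 114 against 152 to 179. Among peaks above the median strength the X to autosome ratio was 0.163. Peaks at X genes included that at Stag2 (862), a cohesin gene. The Y chromosome carried 11 peaks, all between 90718852 and 90811352. Their median strength was 527, above the 152 to 179 of autosomes, and whether reads there map only to Y was not tested.

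**Figure D5:**
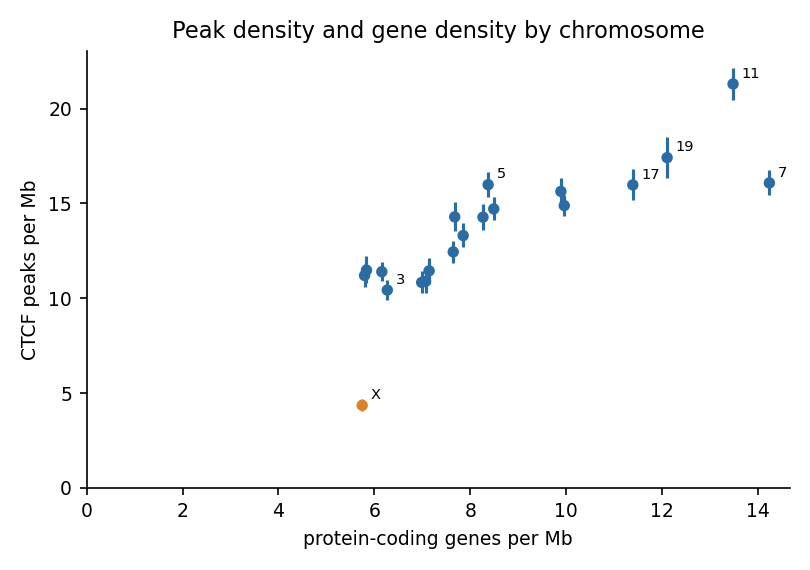
CTCF peaks per Mb (vertical axis, with exact Poisson 95% intervals) against protein-coding genes per Mb (horizontal axis) for the autosomes (blue) and X (orange); the Y chromosome is not drawn. Chromosome 11 had 21.3 peaks per Mb and X had 4.35.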

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

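Tests chosen only after the result was seen were those on strength deciles, on active against developmental gene ends, on gene density of X and on X strength; the others were fixed first. No biological explanation was tested by a comparison between groups, since the samples form 1 condition.

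The comparisons above leave out 5 peaks on unplaced contigs. The strongest, on JH584304.1 from 58729 to 60270, had a joint strength of 5231, the second highest of the whole list, with 962 in the first replicate column and 4269 in the second. The other 4 had strengths from 104 to 318.

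Gene ends against intergenic peaks pointed opposite ways in the replicate columns. A difference in depth or strength that scales all peaks alike was argued against. Within each of 10 deciles of joint strength the median log2 ratio of second over first column was lower at gene ends, by −2.02 to −1.13. This largely restates the pattern, since the difference over all peaks was −1.86. Whether depth acts unequally on the 2 classes was not tested, so depth itself is not excluded. Differently paired peaks were argued against too, since the difference was −1.89 among peaks with summits within 50 bp. Extra reads from active gene ends in the first column may be a cause and stay open. End peaks of ribosomal protein and housekeeping genes (70 peaks) differed from those of protocadherin and Hox genes (33 peaks) by −0.043, bootstrap interval −0.98 to 0.50, too wide to decide. Their median log2 ratios were 1.12 and 1.16, against 0.40 at all gene ends. The explanation would put active ends below other gene ends, but the difference from all gene ends was not tested. Expression of these genes was not measured here.

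The X chromosome carried few peaks. Lower gene density was argued against, as X lay −4.71 residual SDs from the autosomal fit (4.35 observed, 11.1 fitted). Repeated gene families were argued against as the whole cause: without predicted genes and families of 5 or more, 17.9% of X genes had an end peak (exact 95% interval 13.8 to 22.6), against 30.5% on the lowest autosome. A lower dosage of X stays open. The median strength of X peaks was 0.75 of the lowest autosome's, and lower in both columns (19.7 against 28.2, and 91.6 against 117), which restates the pattern and decides nothing. The sex of the embryos is not used here, and mappability was not tested.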

How the results depend on the processing

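Chosen after the data were seen were the unshared ends, the length-matched and trimmed ribosomal lists, and, outside the strength comparison, the peaks above the median of 1 replicate column.
Of 236 values under an alternative setting, 178 kept their direction and side of the threshold or their range and 30 changed sign, among the former all 15 of the gene length trends; the cause was not tested for others unless named.
Peaks above the median strength gave 16910 peaks, an excess inside genes of 1.04 and other genes at 0.96, neither of which passed (permutation), long neuronal genes 12.6 points above other genes (Fisher exact test, adjusted p = 0.132), and strength differences from intergenic peaks of 115 (gene ends), 8.87 (inside genes) and 31.8 (other genes); selecting on strength changes that comparison by construction. List differences that changed sign without passing in either setting were 3.05 (Hox), −1.40 (housekeeping), 0.092 (inhibitory) and −8.25 points (astrocyte) above the median strength. Astrocyte genes stood at −3.32 with an IDR of 0.01 and −13.7 with 500 bp. An IDR of 0.01, a cut that also selects on strength, gave 14.5 at gene ends. It gave an X to autosome ratio of 0.278, against 0.163 above the median strength. By the columns alone the ratio was 0.173 and 0.179. Counting any base gave −3.22 at gene ends (permutation, adjusted p = 0.351) and 40.7 points for activity-regulated genes. With 5 kb the share inside genes was 0.94-fold, and the strength difference at gene ends was −4.79, not passing (permutation, adjusted p = 0.274). List differences were 35.4 (activity-regulated), 20.6 (Hox), 24.4 (housekeeping) and −7.59 points (Zfp), and, not passing, −3.67 (cohesin, CTCF and topoisomerases) and 8.73 (inhibitory).
Shifts compare a list with moved peaks, not with other genes, so most lists pass by construction: 41.2 (activity-regulated), 16.9 (Hox), 37.975 (imprinted), 32.2 (housekeeping), 28.2 (cohesin, CTCF and topoisomerases), 24.5 (excitatory), 20.1 (inhibitory), 27.3 (astrocyte), 41.2 (oligodendrocyte) and 21.6 points (Zfp), while microglial genes at 7.79 did not pass. Unshared ends gave 22.7 points for activity-regulated genes and 12.4 for protocadherins. Of these, the gamma genes share an end, and Pcdha4, Pcdha6 and Pcdha7 share theirs with predicted genes. Excitatory (−0.67) and inhibitory genes (0.998) changed sign. Length-matched lists gave −1.77 for cohesin, CTCF and topoisomerases and −7.50 for excitatory genes.
Above the median of the second column, protocadherins stood at −11.4 points, passing in the opposite direction (Fisher exact test, adjusted p = 0.021; 21.1 by the first, also passing), ribosomal protein genes at 17.6 (10.6 by the first, both passing), long neuronal genes at 6.89, not passing (34.0 by the first, passing) and other genes at 0.99, not passing (0.89 by the first); the class inside genes stood at 1.01 by the first and 1.05 by the second. The protocadherin excess by the first column rests mainly on the peak that the gamma genes share. By the first and second column, Hox genes stood at −5.72 and 2.27, imprinted at 10.2 and −0.62, housekeeping at −2.18 and 0.39, and astrocyte genes at −7.77 and −6.46 points. Strength differences by the first column were 26.2, 1.11 and 3.98, all passing, and by the second −49.4, −29.9 and −0.93, the last not passing, for gene ends, inside genes and other genes (permutation).
No paired analysis was possible because the list holds no input values and no comparison between groups. Start sites per transcript, motif settings, CpG matching and full chromosome lengths were not run, as no genome was used here; depth limits could not be given, since the list holds no read counts.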

Other observations

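All observations here were chosen after the data were seen, apart from the tRNA tests, which were fixed before their results.

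Beyond the fixed lists, 104 families of protein-coding genes with at least 20 members and a common symbol root were compared with other genes for end peaks; 9 were higher and 19 lower after adjustment (Fisher exact tests, Benjamini-Hochberg). Higher families included Mfsd transporters (13 of 21), Taf subunits of the general transcription machinery (14 of 24), Cdk genes (14 of 26), Fbxo genes (19 of 36) and genes with a Ube symbol (21 of 41), each with an adjusted p from 0.015 to 0.035. Lower ones included hair keratin-associated Krtap genes (0 of 56), Pramel genes (0 of 47), alpha defensins (0 of 29), placental prolactin-family Prl genes (0 of 26) and Serpina genes (0 of 24), with adjusted p from 6.6e-07 to 0.0047. Fbxw genes, F-box genes like Fbxo, were lower with 1 of 24 (Fisher exact test, adjusted p = 0.024). Reproductive homeobox Rhox genes, a cluster on X, had 1 of 33. Members of a family often sit in 1 cluster and are not independent.

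The longest stretch without a peak lay on X between 23813432 and 35683553, 11.9 Mb with 51 protein-coding genes. Of these, 30 were predicted genes with a Gm symbol, and whether reads map uniquely there was not tested. Of the 10 longest stretches 5 were on X, and 2 on chromosome 7 held mainly Vmn receptor genes, 46 of 59 and 84 of 103 genes.

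Transfer RNA genes often had a peak. Within 1 kb lay a peak at 92 of 403 (22.8%), against 2.71% ± 1.14 after shifting, 8.43-fold. Long non-coding RNA genes stood at 14.8% (2.87-fold) and pseudogenes at 2.65% (0.70-fold; permutation, adjusted p = 0.0027 for all 3, 8 classes tested). Nearness to protein-coding genes was argued against: of 297 tRNA genes over 5 kb from any such end, 19.2% had a peak, against 2.57% shifted (permutation p = 0.002). Counting of few peaks for many genes was argued against as well, as 36.2% of 174 clusters had a peak, against 4.65% (200 shifts, permutation p = 0.00995). What holds CTCF signal at tRNA genes, or whether these peaks carry a CTCF motif, could not be tested here.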
